A study of Caenorhabditis elegans with 6 samples.

How the data were processed

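Gene expression was measured by RNA sequencing in whole young adults of the wild-type *Caenorhabditis elegans* strain N2 that had fed on 1 of 2 bacterial diets, Comamonas DA1877 or *E. coli* OP50. There were 3 libraries per diet and 6 in all. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a stranded kit that selects messenger RNA. Groups and replicate numbers were taken from the sample titles. No label says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be partly technical.

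The deposited table gives transcripts per 1000000 (TPM) for each gene in each library, made by the authors, and each of the 6 columns sums to 1000000. The authors' mean TPM of each diet and their ratio of the 2 means stand in further columns of the deposited table. Both were recomputed from the 6 libraries and matched within a relative difference of 1.8e-07 for the means and 3.4e-07 for the ratio. Per the submitters' processing notes, the tools were bcl2fastq 2.2.0, Trimmomatic, HISAT2, featureCounts and DESeq2, and the builds WBcel235 and ce11. The notes as used here give neither the role nor the order of the tools. How TPM was computed, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Members of near-identical families are therefore uncertain one by one.

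The table has 23191 gene rows, of which 20616 hold values and 2575 are blank. Blank genes are short: among those with an annotated length the median summed exon length is 123 bp, and 96.5% are at most 250 bp long, against 0.715% of the genes with values. Most of the shortest genes therefore have no value here. Of the genes with values, 20568 matched the Ensembl annotation of WBcel235 by identifier and 48 did not; symbols and coordinates (1-based) come from that annotation.

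TPM keeps no depth, but low values fall on steps. When multiplied by the exon length less 210 to 230 bp, 58.7% to 64.0% of the low values in a library lay within 0.1 of a whole number of reads, against 20.0% by chance. From these steps the libraries hold an estimated 20.6 to 27.8 times 1e+06 assigned reads, and 1 read on a gene of 1000 bp corresponds to 0.0324 to 0.0476 TPM. Counts were not recovered, because too many values lay off the steps, and no count test was run.

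Before the data were examined, a quasi-likelihood count test had been chosen for counts, with limma-trend as the test for normalized values. As the values are TPM, limma-trend was used throughout, on log2(TPM + 0.5), with diet as the only term and all 6 libraries. Genes with at least 1 TPM in at least 3 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are DA1877 over OP50 on the log2(TPM + 0.5) scale, which understates the change of low genes; each comes with limma's moderated standard error (SE). Means are given with the SD over 3 libraries.

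The 42 gene lists were also fixed before the data were examined and cover lipid, one-carbon and propionate metabolism, diet and stress responses, and markers of stage, tissue and RNA quality. Each was tested as a set with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 42 lists. Alternatives were camera with a correlation estimated per list and fry. Of the symbols listed, 10 were not used: some, such as daf-21 and F35E12.5, matched no gene name, and the rest had no value. A gene listed under an unmatched name may thus be missing from its list. Counts per list are given over all genes tested and, beside them, adjusted over the list alone.

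Genes named in the text followed a fixed rule. It took 18 focus genes, the 10 largest increases and 10 largest decreases (adjusted p under 0.05, a mean of at least 10 TPM in the higher diet, no overlap between diets), the 4 members of each list with the smallest p, and every member of lists of 8 or fewer genes. Members of lists that are only counted could be left out, and a gene named outside the rule is marked as chosen after its values were seen.

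The gene and list tests were tested on simulated data with the means and spreads of the 12841 tested genes, 200 of them changed, in 10 simulations. The test recovered 18.0% of genes changed by 0.58 on the log2 scale, 53.3% at 1 and 87.6% at 2, and 4.02% of calls were false. A set of exactly the raised genes was called by camera in 10 of 10 simulations, at an unadjusted p under 0.05. At that threshold 0 of 20 sets of unchanged genes were called. Simulated genes varied independently of each other, which real genes do not. The set result therefore does not show how camera performs on the real lists, whose genes are correlated and can move in both directions.

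Alternatives were pseudocounts of 0.1 and 1, median-of-ratios scaling, upper-quartile scaling, a trimmed-mean scaling without the vitellogenin, major sperm protein, collagen and ribosomal protein genes, no filter, a filter of 5 TPM, a test against a fold of 1.5, the replicate number as a block, and leaving out each library or each replicate number. A fit with each library's sperm-oocyte score as a covariate (mean log2 value of the spermatogenesis list less that of the oocyte list) was added after the data were seen. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.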

Results

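The transcriptomes of *C. elegans* young adults were compared between 2 bacterial diets, to ask how the diet alters transcripts of lipid metabolism and related pathways. *E. coli* OP50 is the standard laboratory food, and Comamonas DA1877 is a bacterium known to supply the worm with more vitamin B12. Each diet had 3 libraries of whole worms. In units of 1e+06 assigned reads, the estimated depth was 20.97, 25.5 and 20.6 for DA1877 replicates 1 to 3 and 27.8, 26.2 and 21.3 for OP50 replicates 1 to 3. Between 11961 and 13007 genes per library reached 1 TPM. Ribosomal protein genes held 34.6% to 40.5% of all TPM.

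On DA1877, all 5 tested enzymes of the propionate shunt, 9 of 14 methionine cycle and folate genes and 19 of 30 oocyte genes fell. Of the pathogen response genes 16 of 23 rose, and so did 18 of 39 glutathione S-transferases and 31 of 33 major sperm protein genes. As lists these 6 passed camera with its preset correlation and not with an estimated one. By fry the shunt (adjusted p = 0.00034), methionine cycle and folate (0.0017), pathogen response (0.000603) and glutathione S-transferase (0.0162) lists passed. The major sperm protein (0.059) and oocyte (0.113) lists did not pass by fry. Of 12841 genes tested, 1878 were higher and 776 lower on DA1877 at an adjusted p under 0.05 (limma-trend), and 1290 were higher and 140 lower by at least 2-fold. At an unadjusted p under 0.05 by limma there were 5092 of the 12841 genes in the main fit. Counts in a list, by adjusted or unadjusted p, are to be read beside these shares of all tested genes. For unadjusted counts of the other fits no share over all genes is given. The share of rises by adjusted p was lower among nuclear hormone receptors and cuticle collagens than the 1878 of 12841 over all genes. The first principal component held 64.6% of the variance and separated the diets, with DA1877 replicate 3 at 19.5, nearest to OP50, and the other DA1877 libraries at 42.8 and 49.98. Correlations across genes, which are not independent replicates, were 0.958 to 0.988 between libraries of the same diet and 0.914 to 0.961 between diets. The total of 2654 calls was 834 without DA1877 replicate 1, 421 without DA1877 replicate 2, 4480 without DA1877 replicate 3, 1124 without OP50 replicate 2 and 1234 without OP50 replicate 3. The number of lower genes was 1305 with median-of-ratios scaling, 1283 with the trimmed-mean scaling, 1176 with upper-quartile scaling and 390 with no filter.

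The largest increases lay in a gene cluster on chromosome V. pud-3 (WBGene00017501, V, 2324634 to 2325152, WBcel235) was at 537 ± 165 TPM on DA1877 and 2.104 ± 1.16 on OP50 (SD, n = 3 each), a log2 fold change of 7.74 ± 0.367 (SE, limma adjusted p = 6.68e-05). Its neighbour pud-4 (V, 2326678 to 2327282) was at 297 ± 108 against 1.14 ± 0.163 TPM, with a log2 fold change of 7.43. Also among the 10 largest increases were pud-2.2 (5.47), pud-2.1 (5.13), pud-1.2 (4.94) and pud-1.1 (4.75), all between 2322038 and 2330930 on V. Reads may be split between pud-1.1 and pud-1.2 and between pud-2.1 and pud-2.2. The remaining 4 were T24B8.5 and irg-5, both pathogen response genes, the glutathione S-transferase gst-38 and Y47H10A.5. The 10 largest decreases were acdh-1, acdh-2, C52B11.5, clec-47, F15E6.4, acs-2, C54F6.5, cyp-35A3, C09B8.4 and hphd-1. C52B11.5 and C54F6.5 were listed at 0 in all 3 DA1877 libraries, against 14.8 ± 3.39 and 11.4 ± 2.93 TPM on OP50, so no fold is given. With the sperm-oocyte score of each library as a covariate, 16 of these 20 genes remained past the threshold.

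All 5 tested enzymes of the propionate shunt, the vitamin B12-independent route of propionate breakdown, fell on DA1877 (median log2 fold change -2.32, camera adjusted p = 1.7e-08, adjusted p = 0.224 with an estimated correlation). The first enzyme of the shunt, the acyl-CoA dehydrogenase acdh-1 (WBGene00016943, I, 6497436 to 6499560), was at 0.782 ± 0.573 TPM on DA1877 and 750 ± 109 on OP50, a log2 fold change of -9.28 ± 0.295 (SE, limma adjusted p = 1.54e-05). hphd-1, a dehydrogenase further along, was at 24.7 ± 2.75 against 319 ± 27.2 TPM (-3.67 ± 0.114, adjusted p = 1.54e-05). The log2 fold changes of hach-1, ech-6 and alh-8 were -2.32, -2.27 and -0.72. The count adjusted over the list alone was also 5, and 5 were called whichever single library was left out. Of the 6 genes of the B12-dependent route, 1 fell: mmaa-1, at 29.4 ± 5.95 against 64.6 ± 5.399 TPM (adjusted p = 0.0056). The count adjusted over the list alone was also 1. The log2 fold change of mmaa-1 was -1.14, and -0.73 ± 0.252 (adjusted p = 0.416) with the sperm-oocyte score as a covariate. In that fit 0 of the 6 passed by limma, with 1 lower at an unadjusted p under 0.05. mmcm-1, the methylmalonyl-CoA mutase, was at 40.5 ± 4.20 and 48.9 ± 2.57 TPM (adjusted p = 0.11), and mce-1, mmab-1, pcca-1 and pccb-1 did not pass. That list passed camera (adjusted p = 0.0484, adjusted p = 0.85 with an estimated correlation) but not without DA1877 replicate 1 (0.0747), DA1877 replicate 2 (0.0575), OP50 replicate 1 (0.0556) or OP50 replicate 3 (0.0793). It did not pass camera with the replicate block either (0.0574).

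**Figure D1:**
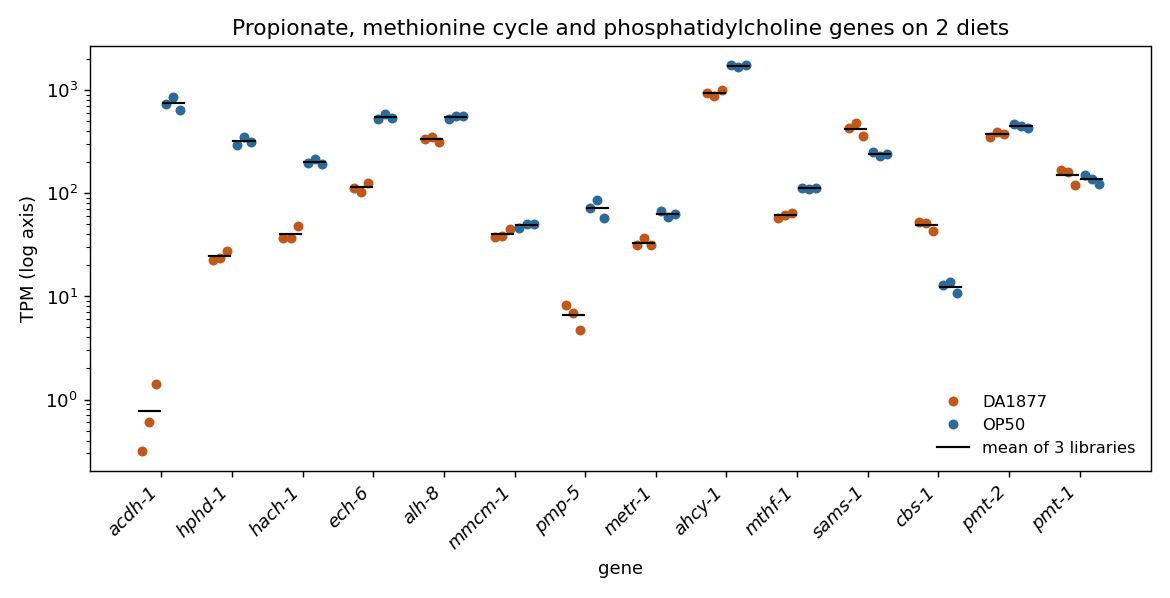
TPM on a log axis of 14 genes in each of the 3 DA1877 (orange) and 3 OP50 (blue) libraries, with black bars at the mean of each diet. acdh-1 lies between 0.315 and 1.42 TPM on DA1877 and between 648 and 865 TPM on OP50, and sams-1 and cbs-1 lie higher on DA1877 in all 3 libraries.

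Methionine and S-adenosylmethionine (SAM) cycle and folate genes moved mostly down: of 14 tested, 9 fell and 1 rose (9 and 2 adjusted over the list alone). The list's median was -0.70 (camera adjusted p = 4.21e-05, adjusted p = 0.224 with an estimated correlation). metr-1, the B12-dependent methionine synthase, was at 33.2 ± 3.04 TPM on DA1877 and 62.9 ± 4.22 on OP50 (-0.92 ± 0.108, limma adjusted p = 0.00319). The methylenetetrahydrofolate reductase mthf-1 was at 61.5 ± 3.33 against 112 ± 0.710 TPM (-0.86), and the S-adenosylhomocysteine hydrolase ahcy-1 at 939 ± 60.2 against 1727 ± 42 TPM (-0.88). The transporter gene pmp-5 fell by 3.35 on the log2 scale. sams-1, a SAM synthetase, rose from 242 ± 11.8 TPM on OP50 to 424 ± 61.1 on DA1877 (0.80 ± 0.117, adjusted p = 0.00746). Its paralog sams-3 fell (-0.55), while sams-5 (0.90, adjusted p = 0.0518) and sams-4 (-0.30, adjusted p = 0.13) did not pass. Reads may be shared among the 4 sams genes, and sams-3, sams-4 and sams-5 were chosen after their values were seen. With the sperm-oocyte score as a covariate 1 gene of the list fell, pmp-5 (-4.13 ± 0.326), while the log2 fold changes of metr-1 and ahcy-1 stayed at -1.06 ± 0.189 and -0.77 ± 0.137 with larger SEs than the 0.108 and 0.0768 without it. That of sams-1 was 0.51 ± 0.197. Among 11 transsulfuration and cysteine genes 4 rose and 1 fell, also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.485). Without DA1877 replicate 1 or DA1877 replicate 2, 2 rose. The gene that fell, cysl-3 (-0.49), did not pass without DA1877 replicate 1 (limma adjusted p = 0.066), DA1877 replicate 2 (0.0832) or OP50 replicate 3 (0.0565). The cystathionine beta-synthase cbs-1 was at 49.4 ± 5.29 against 12.5 ± 1.57 TPM (1.95, adjusted p = 0.00039). In the 7 genes of glycine cleavage and serine 1 fell, mel-32 (-0.45), also adjusted over the list alone, and the list did not pass camera (adjusted p = 0.877). The mel-32 call was lost without DA1877 replicate 1 (0.0661), DA1877 replicate 2 (0.0848) or OP50 replicate 2 (0.0529), and with the covariate mel-32 was at -0.25 ± 0.137 on the log2 scale (0.64).

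Genes of phosphatidylcholine synthesis, the pathway named in the series title, showed few calls: 1 of 17 tested fell and 0 rose (0 in either direction adjusted over the list alone, and 6 at an unadjusted p under 0.05 by limma). The unadjusted share is below the 5092 of 12841 among all tested genes. The phosphoethanolamine methyltransferases pmt-1 and pmt-2 were at 151 ± 25.3 and 374 ± 19.6 TPM on DA1877 and at 137 ± 12.64 and 452 ± 23.7 on OP50, with adjusted p of 0.537 and 0.0523. pcyt-1, a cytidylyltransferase of the choline branch, was at 35.5 ± 5.86 against 25.7 ± 3.40 TPM (adjusted p = 0.0791). The gene that fell was the phosphatidate phosphatase lpin-1 (-0.44, adjusted p = 0.0273), and its adjusted p was 0.106, 0.087, 0.058 and 0.0791 without DA1877 replicate 1, DA1877 replicate 2, OP50 replicate 1 and OP50 replicate 2. The list had a median of 0.04 and a camera adjusted p of 0.685 in the lower direction, so median and test differed in sign.

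Among 22 genes of fatty acid synthesis, desaturation and elongation, 4 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.601). These counts were 2 and 1 without DA1877 replicate 1, 0 and 1 without DA1877 replicate 2, 9 and 5 without DA1877 replicate 3, 3 and 1 without OP50 replicate 2 and 1 and 2 without OP50 replicate 3. Of the delta-9 desaturases, fat-7 was at 14.6 ± 5.98 TPM on DA1877 and 110 ± 55.1 on OP50 (-2.84 ± 0.387, limma adjusted p = 0.00587), and fat-5 at 4.90 ± 4.20 against 14.6 ± 3.10 TPM (-1.73, adjusted p = 0.0419). With the sperm-oocyte score as a covariate the log2 fold change of fat-5 was 0.084 ± 0.654 and that of fat-7 -4.44 ± 0.455. fat-6 was higher, at 237 ± 46.8 against 158 ± 13.7 TPM (0.57, adjusted p = 0.0347). fat-6 and fat-7 are close paralogs that may share reads. The fatty acid synthase fasn-1 was at 27.9 ± 2.16 and 25.7 ± 1.28 TPM (adjusted p = 0.476). Of 19 lipid regulators 1 rose and 2 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.266). The SREBP homolog sbp-1 rose (0.62, adjusted p = 0.0492), and nhr-68 (-1.75) and mxl-3 (-1.1) fell. In the fit with the covariate sbp-1 was at 0.078 ± 0.281 (adjusted p = 0.981), nhr-68 at -1.89 ± 0.285 (0.0597) and mxl-3 at -1.66 ± 0.639 (0.487). Without DA1877 replicate 1, DA1877 replicate 2, OP50 replicate 1, OP50 replicate 2 or OP50 replicate 3 in turn, the adjusted p was 0.108, 0.14, 0.0557, 0.129 and 0.113 for fat-5, 0.168, 0.182, 0.0847, 0.097 and 0.141 for sbp-1, and 0.116, 0.0646, 0.0743, 0.0733 and 0.0791 for mxl-3. The fat-6 call was lost without DA1877 replicate 2 (0.0951), OP50 replicate 2 (0.103) or OP50 replicate 3 (0.105).

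Triglyceride synthesis and lipid droplet genes gave 3 rises and 1 fall among 17, also adjusted over the list alone. dgat-2, a diacylglycerol acyltransferase, was at 28.9 ± 8.65 TPM on DA1877 and 9.71 ± 1.57 on OP50 (1.5, limma adjusted p = 0.00908). dhs-3 and acs-22 rose by 1.31 and 1.33 on the log2 scale. The gene that fell was acl-3 (-0.48), with adjusted p of 0.143, 0.129, 0.0508, 0.102 and 0.0887 without DA1877 replicate 1, DA1877 replicate 2, OP50 replicate 1, OP50 replicate 2 and OP50 replicate 3, and its log2 fold change was -0.31 ± 0.23 (0.758) with the sperm-oocyte covariate. That list's median was -0.17, its mean 0.08 and its camera adjusted p 0.685. Among 9 lipases 4 rose and 2 fell, also adjusted over the list alone. lipl-2 (2.98), lipl-5 (1.92) and lipl-1 (1.87) rose, and hosl-1 was lower (-0.81) but not without DA1877 replicate 1 (adjusted p = 0.0699), DA1877 replicate 2 (0.101) or OP50 replicate 2 (0.0561). The lipase list had a camera adjusted p of 0.231 and a fry adjusted p of 0.0443. lipl-4 lay below the filter, with 0.190 ± 0.231 and 0.0746 ± 0.101 TPM, and was not tested. In mitochondrial beta-oxidation 4 of 25 genes rose and 5 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.748, median 0.03, mean -0.18). The rises were 1 without DA1877 replicate 2, and the falls were 3 without OP50 replicate 1 and 2 without OP50 replicate 2 or OP50 replicate 3. The acyl-CoA synthetase acs-2 was at 0.440 ± 0.204 against 24.2 ± 7.02 TPM (-4.70 ± 0.255, adjusted p = 0.000123). acdh-2, a paralog of acdh-1, was at 0.0334 ± 0.0179 against 24.7 ± 6.87 TPM, and the carnitine palmitoyltransferase cpt-4 rose (2.74).

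Peroxisomal beta-oxidation and ascaroside genes rose in 8 of 18 cases and fell in 0 (11 and 0 adjusted over the list alone). The list's median was 0.63 (camera adjusted p = 0.000107, adjusted p = 0.763 with an estimated correlation). Among the 8 were maoc-1 (0.98), dhs-28 (0.73), acs-7 (1.09) and ctl-2, a peroxisomal catalase (0.73). The number of peroxisomal rises was 4 without DA1877 replicate 1, DA1877 replicate 2 or OP50 replicate 3 and 5 without OP50 replicate 2. With the sperm-oocyte score as a covariate it was 0 by limma, with 7 at an unadjusted p under 0.05. In that fit the log2 fold changes of maoc-1 and acs-7 were 0.94 ± 0.281 and 1.48 ± 0.283, against SEs of 0.14 and 0.166 without the covariate. Sphingolipid genes rose in 7 and fell in 1 of 28 cases (9 and 1 adjusted over the list alone, camera adjusted p = 0.0605), and rose in 4 without DA1877 replicate 2. The acid sphingomyelinase asm-3 was at 9.94 ± 1.87 against 1.96 ± 0.585 TPM (2.099 ± 0.234, limma adjusted p = 0.00259), and gba-4 rose (2.01). The sphingolipid list passed with median-of-ratios (adjusted p = 0.0303), upper-quartile (0.0213) and trimmed-mean scaling (0.022), and without DA1877 replicate 1 (0.0415), DA1877 replicate 3 (0.0278) or OP50 replicate 2 (0.00823). Of 11 genes of branched-chain amino acid breakdown 0 passed, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 by limma (camera adjusted p = 0.685).

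The vitellogenin genes, which encode yolk proteins, rose in 3 of 6 cases, also when adjusted over the list alone. vit-1 was at 878 ± 222 TPM on DA1877 and 437 ± 127 on OP50 (1.01, limma adjusted p = 0.026), vit-4 at 612 ± 200 against 331 ± 63.7 and vit-3 at 709 ± 211 against 402 ± 94.2. vit-2 was at 3152 ± 584 against 2775 ± 397 TPM (adjusted p = 0.412), and vit-5 (adjusted p = 0.431) and vit-6 (0.289) also did not pass. vit-3, vit-4 and vit-5 are similar in sequence, so reads may be shared. The number of vitellogenin calls by limma was 0 without DA1877 replicate 2, OP50 replicate 1 or OP50 replicate 2, with 3 at an unadjusted p under 0.05 each time. With the sperm-oocyte covariate the log2 fold changes of vit-1, vit-3 and vit-4 were 2.03 ± 0.225, 1.80 ± 0.224 and 1.83 ± 0.244, against 1.01, 0.80 and 0.86. The list's camera adjusted p was 0.0512, and below the threshold with the replicate block (0.00222) and without DA1877 replicate 1 (0.00433), DA1877 replicate 2 (0.0188) or OP50 replicate 3 (0.00263).

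Pathogen response genes rose together: 16 of 23 were higher and 0 lower (18 and 1 adjusted over the list alone). The list's median was 1.99 (camera adjusted p = 1.75e-11, adjusted p = 0.224 with an estimated correlation). T24B8.5, a gene induced in the p38 immune pathway, was at 71.6 ± 16.96 TPM on DA1877 and 1.83 ± 0.226 on OP50 (4.93 ± 0.192, limma adjusted p = 3.14e-05). irg-5 was at 158 ± 89.1 against 7.78 ± 5.08 TPM (4.23), and C17H12.8 and dod-22 rose by log2 fold changes of 2.84 and 2.99. The lysozyme lys-2 was at 159 ± 3.01 against 15.8 ± 1.34 TPM (3.30 ± 0.0982, adjusted p = 1.54e-05), whereas lys-4 was at 16.6 ± 2.39 against 181 ± 48.3 TPM (-3.38, adjusted p = 0.000194). Of 26 lysozymes and saposins 10 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.000927, adjusted p = 0.85 with an estimated correlation). The falls were 1 without OP50 replicate 1, OP50 replicate 2 or OP50 replicate 3. C-type lectins went both ways, with 31 of 89 higher and 11 lower (35 and 16 adjusted over the list alone, camera adjusted p = 0.0222, adjusted p = 0.85 with an estimated correlation), clec-41 rising (2.53) and clec-47 falling (-4.89). The lectin counts were 17 and 5 without DA1877 replicate 1, 12 and 5 without DA1877 replicate 2, 20 and 0 without OP50 replicate 2 and 22 and 2 without OP50 replicate 3. The lectin list did not pass camera without DA1877 replicate 1 (adjusted p = 0.0926), without DA1877 replicate 2 (0.0864) or with no filter (0.67). With the sperm-oocyte score as a covariate, 0 lectin genes passed by limma, with 17 higher and 8 lower at an unadjusted p under 0.05. In that fit the log2 fold changes of clec-41 and clec-47 were 2.04 ± 0.294 and -5.05 ± 0.738, against SEs of 0.176 and 0.338 without the covariate.

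Glutathione S-transferases rose in 18 and fell in 1 of 39 cases (20 and 1 adjusted over the list alone). The list's median was 0.46 (camera adjusted p = 5.42e-07, adjusted p = 0.85 with an estimated correlation). gst-38 was at 80.5 ± 8.09 TPM on DA1877 and 2.35 ± 0.623 on OP50 (4.85 ± 0.185, limma adjusted p = 3.14e-05), and gst-28 (2.18), gst-13 (1.75) and gst-10 (1.48) also rose. Without DA1877 replicate 2, 11 rose. Cytochrome P450 genes gave 10 higher and 8 lower of 42 (12 and 8 adjusted over the list alone, camera adjusted p = 0.485). cyp-35A3 was at 2.94 ± 1.48 against 58.5 ± 23.8 TPM (-4.13, adjusted p = 0.00131), its paralog cyp-35A2 fell (-2.47) and cyp-14A5 rose (2.24). UDP-glucuronosyltransferases gave 8 higher and 6 lower of 47 (11 and 8 adjusted over the list alone, camera adjusted p = 0.243), with ugt-44 rising (1.80) and ugt-8 falling (-1.63). Among 136 nuclear hormone receptors 8 rose and 6 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.35), with nhr-114 at -1.79 and nhr-8 at 1.42 on the log2 scale. DAF-16 target genes rose in 8 and fell in 2 of 24 cases (9 and 2 adjusted over the list alone, camera adjusted p = 0.112), with ins-7 (2.06) and dod-17 (1.48) among the rises. The list was not split by whether DAF-16 raises or lowers a target, so the counts give no direction of its activity. With the covariate 1 of the DAF-16 targets passed, and ins-7 was at 2.58 ± 0.649 (adjusted p = 0.232) and dod-17 at 0.55 ± 0.24 (0.555). Counts of cytochrome P450, UDP-glucuronosyltransferase, nuclear hormone receptor and DAF-16 target rises were 4, 4, 1 and 4 without DA1877 replicate 1, 2, 3, 1 and 5 without DA1877 replicate 2, and 5, 10, 12 and 8 without DA1877 replicate 3. They were 7, 5, 3 and 8 without OP50 replicate 1, 7, 9, 6 and 5 without OP50 replicate 2 and 6, 5, 2 and 5 without OP50 replicate 3.

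Sperm and oocyte transcripts moved in opposite directions. Major sperm protein genes rose in 31 of 33 cases, also adjusted over the list alone (median 1.33, camera adjusted p = 3.31e-15, adjusted p = 0.85 with an estimated correlation). msp-64 was at 581 ± 109 TPM on DA1877 and 197 ± 50.6 on OP50 (1.57 ± 0.210, limma adjusted p = 0.0055). Reads may be shared within this family of near-identical genes. Their summed share of TPM was 1.64%, 1.51% and 1.14% on DA1877 and 0.799%, 0.560% and 0.426% on OP50. Of 36 further spermatogenesis genes 25 rose and 1 fell (30 and 2 adjusted over the list alone, median 1.17, camera adjusted p = 6.02e-09, adjusted p = 0.85 with an estimated correlation). ssp-9 rose (1.77). The gene that fell was fog-1, which promotes sperm fate (-0.54), named here because it stood alone and chosen after its values were seen. Oocyte and eggshell genes fell in 19 of 30 cases and rose in 0 (28 and 0 adjusted over the list alone, median -0.63, camera adjusted p = 2e-09, adjusted p = 0.85 with an estimated correlation). Among the 19 were nos-2 (-1.08), spn-4 (-0.85), puf-5 (-0.78) and egg-4 (-0.72). In the fit with the sperm-oocyte covariate, which is built from the spermatogenesis and oocyte lists, msp-64 was at 0.60 ± 0.129, nos-2 at -0.30 ± 0.282, spn-4 at -0.22 ± 0.28, puf-5 at -0.041 ± 0.176 and egg-4 at -0.40 ± 0.196. The counts for major sperm protein, other spermatogenesis and oocyte genes were 14, 4 and 0 without DA1877 replicate 2 and 16, 9 and 1 without OP50 replicate 2. Without DA1877 replicate 1 they were 26, 13 and 2, and without OP50 replicate 3, 29, 18 and 2.

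**Figure D2:**
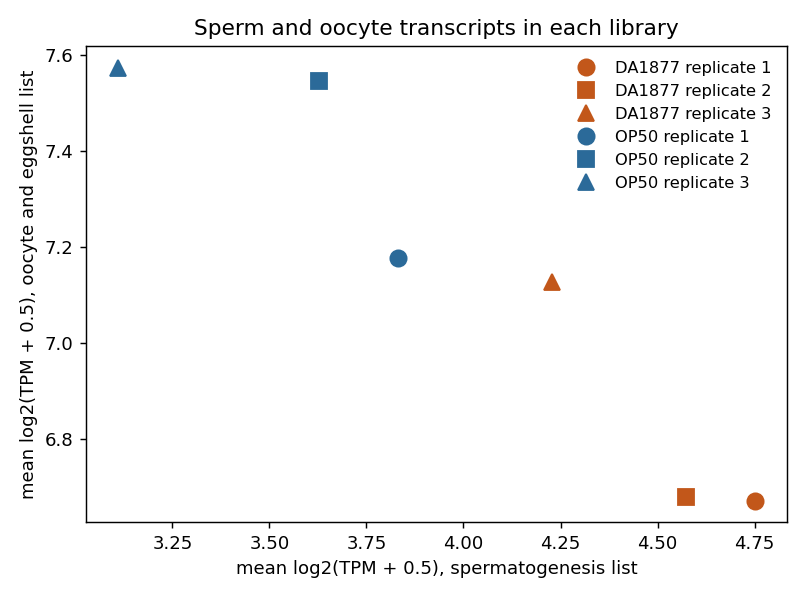
Mean log2(TPM + 0.5) of the oocyte and eggshell list (vertical axis) against that of the spermatogenesis list (horizontal axis), 1 point per library, coloured by diet and shaped by replicate number. DA1877 libraries lie between 4.23 and 4.75 on the sperm axis and OP50 libraries between 3.11 and 3.83, and DA1877 replicate 3 lies nearest to OP50.

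Early embryo genes fell in 3 of 12 cases and rose in 0 (3 and 1 adjusted over the list alone, median -0.81, camera adjusted p = 0.0169, adjusted p = 0.85 with an estimated correlation). The 3 were tbx-9, pal-1 and skr-7, and the list missed the threshold without DA1877 replicate 3 (0.0561), OP50 replicate 2 (0.0694) or OP50 replicate 3 (0.128). Of these embryo genes 0 passed by limma without DA1877 replicate 1 or DA1877 replicate 2, with 3 lower and 1 higher at an unadjusted p under 0.05, and 1 passed without OP50 replicate 2 or OP50 replicate 3, 5 without DA1877 replicate 3 and 6 without OP50 replicate 1. The early embryo median was 0.714 with the sperm-oocyte score as a covariate, and that of the oocyte list 0.071. In that fit the log2 fold changes of tbx-9, pal-1 and skr-7 were -0.33 ± 0.205, -0.11 ± 0.17 and 0.043 ± 0.179, against -0.78, -0.63 and -0.94. Among 30 general germline genes 0 passed by limma and 0 adjusted over the list alone. At an unadjusted p under 0.05 by limma there were 12, a share similar to the 5092 of 12841 among all tested genes. The germline list nonetheless passed camera with a median of -0.26 (adjusted p = 0.00771, adjusted p = 0.85 with an estimated correlation). Without DA1877 replicate 3, 10 general germline genes fell, and 1 fell without OP50 replicate 1. The germline median was 0.049 with the covariate.

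Muscle genes rose in 3 of 23 cases, also adjusted over the list alone (median 0.23, camera adjusted p = 0.00537, adjusted p = 0.85 with an estimated correlation). That share is similar to the 1878 of 12841 among all tested genes. mup-2, troponin T, was at 726 ± 83.7 TPM on DA1877 and 317 ± 23.3 on OP50 (1.19, limma adjusted p = 0.00123). Intestine genes gave 6 rises and 2 falls of 25 (10 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 0.0522 and 0.0311 with the replicate block), with asp-3 at 697 ± 8.90 against 453 ± 42.7 TPM (0.63). Among the falls was pgp-1 (-0.99). It did not pass without DA1877 replicate 1 (limma adjusted p = 0.0575), DA1877 replicate 2 (0.107), OP50 replicate 1 (0.0634) or OP50 replicate 2 (0.0806). Mitochondrially encoded genes rose in 5 of 12 cases (9 adjusted over the list alone, median 0.71, camera adjusted p = 0.000124, adjusted p = 0.85 with an estimated correlation). ctc-3 was at 629 ± 57.8 against 297 ± 39 TPM (1.08, adjusted p = 0.00248). The summed share of mitochondrially encoded genes was 0.357%, 0.292% and 0.319% of TPM on DA1877 and 0.315%, 0.167% and 0.165% on OP50. OP50 replicate 1 thus lay within the range of DA1877. Those muscle, intestine and mitochondrial counts of rises were 2, 1 and 2 without DA1877 replicate 2 and 2, 2 and 2 without OP50 replicate 2. They were 2, 2 and 3 without DA1877 replicate 1, 8, 12 and 6 without DA1877 replicate 3, 3, 2 and 9 without OP50 replicate 1 and 2, 3 and 3 without OP50 replicate 3. With the sperm-oocyte score as a covariate they were 0, 1 and 0 by limma, with 3, 5 and 1 higher at an unadjusted p under 0.05, and the muscle median was -0.039. In that fit the log2 fold changes of mup-2 and ctc-3 were 0.81 ± 0.136 and 0.80 ± 0.208, against SEs of 0.109 and 0.119 without the covariate.

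Of 76 cytosolic ribosomal protein genes 1 rose, rpl-42 (0 adjusted over the list alone, median -0.01, camera adjusted p = 0.687). The rpl-42 call was lost without DA1877 replicate 1 (0.0779), DA1877 replicate 2 (0.0864) or OP50 replicate 3 (0.0564). Cuticle collagens gave 9 rises and 3 falls of 121 (2 and 1 adjusted over the list alone, median -0.06 and camera adjusted p = 0.918 in the higher direction). The collagen counts were 3 and 13 without DA1877 replicate 1, 2 and 1 without DA1877 replicate 2 or OP50 replicate 2, 35 and 4 without DA1877 replicate 3, 6 and 6 without OP50 replicate 1 and 4 and 1 without OP50 replicate 3. The list passed camera without DA1877 replicate 1 (adjusted p = 0.00241) or DA1877 replicate 3 (0.000174). By the counts above falls prevailed in the former fit and rises in the latter, so the balance of calls turned on single libraries. In the tricarboxylic acid cycle and glyoxylate shunt 1 of 25 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.826). These were suca-1 and pyc-1, and neither passed without DA1877 replicate 1, DA1877 replicate 2, OP50 replicate 1, OP50 replicate 2 or OP50 replicate 3, with adjusted p of 0.0564 to 0.161 for suca-1 and 0.0519 to 0.103 for pyc-1. Heat shock and ER stress genes rose in 2 of 15 cases, crt-1 and hsp-3, also adjusted over the list alone (median -0.02, mean 0.03, camera adjusted p = 0.685). Without OP50 replicate 2 neither passed (0.0544 for crt-1 and 0.0788 for hsp-3), and hsp-3 did not pass without DA1877 replicate 2 (0.0597) or OP50 replicate 1 (0.0513). Iron and heme genes rose in 1 and fell in 2 of 9 cases, also adjusted over the list alone (camera adjusted p = 0.627). The ferritin ftn-2 was at 542 ± 31.6 TPM on DA1877 and 258 ± 13.8 on OP50 (1.07, limma adjusted p = 0.00063). hrg-1 (-1.87) and hrg-7 (-2.13) fell, but not without OP50 replicate 2 (0.063 and 0.0582). Histone genes gave 1 rise of 23, his-38, also adjusted over the list alone (camera adjusted p = 0.341), and the housekeeping references 1 fall of 9, pmp-3 (0 adjusted over the list alone, camera adjusted p = 0.34). his-38 did not pass without DA1877 replicate 2 (0.0555), nor pmp-3 without DA1877 replicate 1 (0.146), DA1877 replicate 2 (0.18), OP50 replicate 2 (0.137) or OP50 replicate 3 (0.123). With the sperm-oocyte covariate rpl-42 was at 0.51 ± 0.397 against 0.98, pyc-1 at -0.22 ± 0.17 against -0.45 and pmp-3 at -0.084 ± 0.26 against -0.59, while crt-1 was at 0.99 ± 0.142 against 0.59 and hsp-3 at 1.19 ± 0.167 against 0.64. By limma 0 genes passed, over all genes or adjusted over the list alone, among 12 of the mitochondrial stress response, 19 of molting, 20 of neurons and 18 of the pharynx, with 2, 0, 2 and 2 at an unadjusted p under 0.05 and camera adjusted p of 0.485, 0.408, 0.424 and 0.964.

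**Figure D3:**
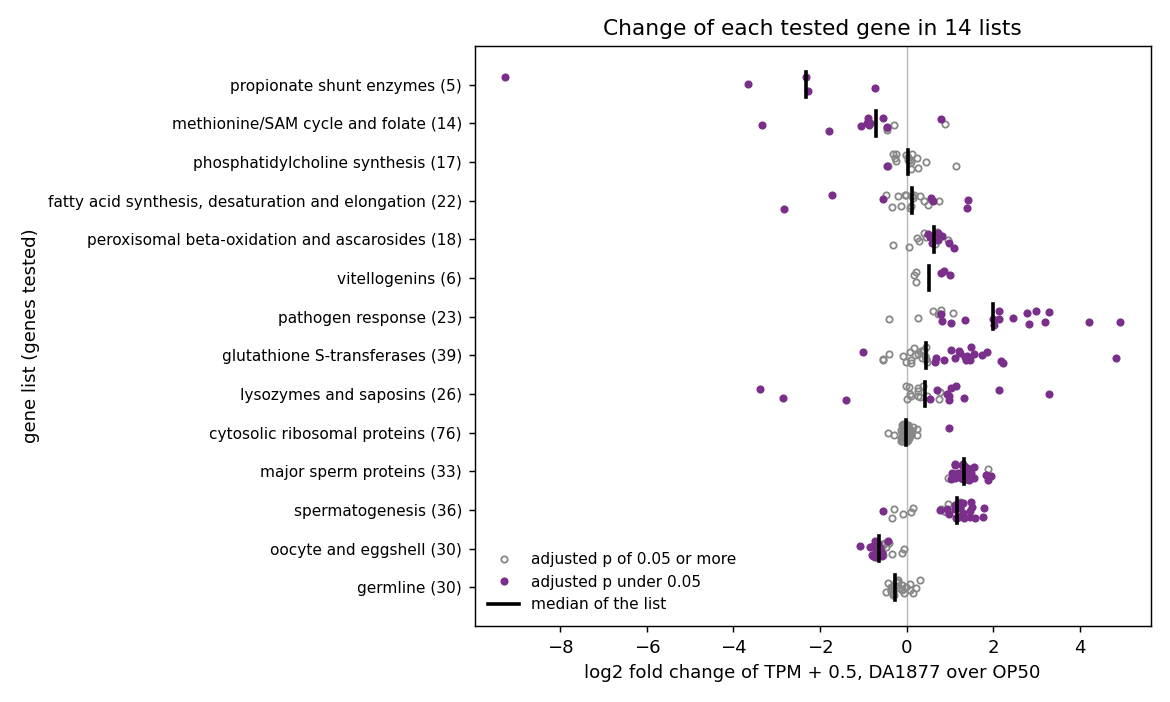
Log2 fold change (DA1877 over OP50, TPM + 0.5) of every tested gene in 14 lists, filled where the limma adjusted p is under 0.05, with a black bar at each list's median and the number of genes tested in parentheses. The medians run from -2.32 for the propionate shunt to 1.99 for the pathogen response, with -0.01 for ribosomal proteins.

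Camera with the preset correlation called 9 lists higher and 6 lower, fry called 5 higher and 2 lower, and with an estimated correlation 0 lists passed in either direction, with 3 of the 42 at an unadjusted p under 0.05. Those higher by fry were the pathogen response, glutathione S-transferase, peroxisomal, lysozyme and saposin, and lipase lists. Those lower by fry were the propionate shunt and the methionine cycle and folate lists. Other splits of the 6 libraries into 3 and 3, each mixing the diets, gave 11 to 19 lists by camera. Sperm and oocyte scores differed between the diets without overlap, and with their difference as a covariate 52 genes were higher and 30 lower on DA1877. In that fit 4 shunt enzymes, the transporter gene pmp-5 of the methionine cycle and folate list, 4 pathogen response genes, 3 glutathione S-transferases and 3 vitellogenins passed. The enzyme genes metr-1, mthf-1 and ahcy-1 of that list did not. Of the major sperm protein, spermatogenesis and oocyte genes 0 passed by limma, with 8, 2 and 2 higher and 0, 1 and 0 lower at an unadjusted p under 0.05.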

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

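The fit with the sperm-oocyte score as a covariate was chosen after the data were seen, and the other alternatives before the data were examined. As the values are TPM, the scalings, the filter of 5 TPM and the test against a fold were then run in a form adapted to them. The quasi-likelihood test chosen for counts and its alternatives, a DESeq2 Wald test and limma-voom, were not run.

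Of the 130 named genes past the threshold, 42 were past it in the same direction under each pseudocount, scaling, filter, block and omission in which they were tested, and 26 also with the covariate. The test against a fold of 1.5 was run for the counts of genes, not for named genes. Genes present on 1 diet only were not tested in settings that left too few libraries at 1 TPM. Both pseudocounts kept all 4 counts of genes within 1.5 times of their main values.

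The number of lower genes, 776 in the main analysis, was 1305 with median-of-ratios scaling, 1176 with upper-quartile scaling, 1283 with the trimmed-mean scaling and 390 with no filter. The scalings moved the median of all genes by at most 0.054 on the log2 scale. With a filter of 5 TPM, which tests 8924 genes, 829 were higher and 78 lower by at least 2-fold, against 1290 and 140. A test against a fold of 1.5 gave 136 higher and 52 lower genes, as that test asks for a larger change. For the lists, 9 higher and 6 lower by camera became 0 and 0 with an estimated correlation and 5 and 2 with fry. Apart from these tests' own constructions and the filter's smaller number of genes, the cause was not tested.

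With the replicate number as a block, 2349 genes were higher and 1457 lower, 3806 in all against 2654 without it. Whether the numbers pair the libraries stays open. The correlations of deviations within replicates 1, 2 and 3 were 0.14, 0.0689 and 0.39. The best partner in the other diet was replicate 2 for replicate 1, replicate 1 for replicate 2 and replicate 3 for replicate 3, in both diets.

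Leaving out libraries or replicate numbers gave 57 to 2266 higher and 17 to 2214 lower genes, and 57 to 1480 higher and 17 to 242 lower by at least 2-fold. The lowest counts came without replicate 2 of both diets and the highest without DA1877 replicate 3. Fewer libraries lower the power of the test, but that does not account for the counts above the main ones, and the cause was not tested.

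With the covariate 52 genes were higher and 30 lower, and 51 and 30 by at least 2-fold. The score does not overlap between the diets, so the covariate takes up much of the diet difference itself. Among named genes past the threshold in the main fit, the covariate reversed the sign for fat-5 (0.084), skr-7 (0.043) and unc-54 (-0.039). Among lists past it, the camera direction or median was reversed for the oocyte (0.071), early embryo (0.714), germline (0.049) and muscle (-0.039) lists. None of these genes and lists passed with the covariate. Genes not past the threshold in the main fit could also change sign, such as pmt-1 (0.13 to -0.44). The cause was not tested.

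Depth limits values far below the filter: 1 read on a gene of 1000 bp was 0.0324 to 0.0476 TPM, so values of a few hundredths of a TPM rest on single reads.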

Other observations

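The tests of the scalings for the sperm and oocyte pattern, of intestinal RNA for sams-1 and of gene families and chromosomes were chosen after the results were seen.

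Among 137 gene families with at least 8 tested members, some held more genes of 1 direction than the other tested genes (one-sided Fisher's exact tests, adjusted over both directions). All 12 ssp genes (adjusted p = 1.27e-08) and all 9 nspd genes (2.75e-06), both known as sperm families, were higher on DA1877, as were 12 of 20 spe genes (0.000169). Nucleoporin genes of the npp family were lower in 10 of 24 cases (3.79e-05, median log2 fold change -0.34), and RNA-binding puf genes in 5 of 9 (0.0028). Members of a family are not independent of each other. By chromosome, 20.2% of tested genes on IV and 8.75% on X were higher on DA1877, with I, II, III and V at 14.3%, 15.3%, 11.5% and 15.8%.

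Sperm genes were higher and oocyte genes lower on DA1877. Scaling is argued against, because the lowest median of the spermatogenesis list under the other scalings was 1.19, and that of the oocyte list lay between -0.62 and -0.58. Males among the DA1877 worms stay open. The median log2 fold change of 14 male-specific genes was -0.16 with a pseudocount of 0.5 and -1.16 with 0.01, neither above 0. Summed levels were 1.91, 1.38 and 0.892 TPM on DA1877 and 4.27, 11.3 and 1.28 on OP50. With 0.01 the median lay below the bound of 0.5 set against males. Yet 0 of these genes reached the filter, so this cannot decide the question: the medians of their means were 0.0667 TPM on DA1877 and 0.144 on OP50, near single reads. With a pseudocount of 0.5 the bound was too high, as doubling each OP50 mean would give a median of 0.29. Worms collected at different points of young adulthood stay open too: the sperm and oocyte scores, as deviations within each diet, had a Pearson r of -0.819 over 6 libraries (exact permutation p = 0.139) and a Spearman rho of -0.886 (p = 0.0833), over 36 permutations, and r was -0.602 without the 2 farthest libraries. That would be consistent with a difference in stage, which the diet may also produce through the rate of development, and these 2 cannot be told apart since no label gives the age in hours.

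Genes higher by at least 2-fold on DA1877 outnumbered those lower by at least 2-fold. Scaling as the cause is argued against by a ratio that stayed at 9.09 or above under the other scalings. Transcripts of the sperm-forming germ line, which are rare from X, are a candidate explanation: 2.72% of the 2-fold higher genes lay on X (35 of 1288) against 14.4% of the other tested genes (1657 of 11524, Fisher's exact p = 1.97e-42), and 2.83% without the sperm lists. Genes that move together are not independent, so the Fisher p-value does not measure the spread between samples. Other germline transcripts are also rare from X, so the test does not single out sperm. A difference in stage stays open here as well.

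sams-1 was higher on DA1877 while most methionine cycle genes were lower. A mere shift of reads between the sams paralogs is argued against, because their summed TPM differed by 0.599 on the log2 scale (506 ± 63.1 against 332 ± 9.30 TPM, n = 3 each, exact permutation p = 0.1, the smallest the design allows). The sum does not show which paralog rose, and how reads that map to several genes were treated is not given. A higher share of intestinal RNA stays open, since the intestine list had a median of 0.437 against 0.80 for sams-1. A response of sams-1 to the diet also stays open and may or may not act through vitamin B12, which was not tested.

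The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1878 higher and 776 lower genes, and 1290 and 140 by at least 2-fold, and the highest count in any other split was 1 for each, so 1 of the 10 splits gave as many. For lists the real split gave 15 and the highest other 19, with 5 of the 10 splits giving as many.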
